A study of Danio rerio with 2 samples.

How the data were processed

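Brains of wild-type male and female zebrafish were compared, each sex as 1 sequencing library from a pool of 5 fish. Per the labels' protocols, total RNA was extracted with TRIzol, samples with an RNA integrity number of 8 to 9 were used, and libraries were prepared from 3 µg of RNA and sequenced as single reads of 51 bp on an Illumina HiSeq instrument. Groups were taken from the sex given in the labels. Per the submitters' processing notes, TopHat 1.4.1, DESeq and the genome build Zv9 were used, with no roles given. The program that counted reads, the annotation and the treatment of reads that match several places are not given in the sources used here, and neither is whether counting used strand, so overlapping and antisense genes cannot be separated.

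The deposited table holds 27423 rows with a symbol, an Entrez ID, coordinates and 4 value columns. Per the file headers 2 of these are raw counts, but they are estimated counts, since only 1.56% of male and 1.92% of female values above 0 were whole within 0.001. Per the file headers the other 2 columns are normalized counts, and their values are on a log2 scale. Each equals the log2 of the deposited raw count divided by 0.971 for the male and 1.03 for the female library, with results under 0 set to 0. Of values under 0.5 of a read, 65 of 125 were whole multiples of 1/76 within 0.0001, which differs from the read length in the labels. The estimated counts were the measure used. They were summed over rows with the same Entrez ID (296 genes with 624 rows) and rounded to whole numbers. Entrez IDs of 2 rows are not numbers, and those rows were kept on their own. Current symbols came from the RefSeq gene table of assembly GRCz12tu by Entrez ID for 22112 of 27095 genes (81.6%), and no coordinate was taken from that assembly. Coordinates are those of the deposited table.

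Counts were scaled with median-of-ratios size factors as DESeq computes them, 0.970 for the male and 1.03 for the female library. The log2 ratio of male over female was taken after adding 0.5 to each count. An exact Clopper-Pearson 95% interval of the male share of a gene's reads was turned into an interval of the ratio. It covers counting error only, since amplified reads carry no molecular identifiers and no biological spread can be estimated from 1 library per sex. No p-value was computed. A gene was called higher in a library under a rule of size: mean of at least 1 CPM (counts scaled by the size factors, as a share of the mean library total), fold of at least 2 and an interval that excludes 1. A count of 0 allows up to 3 reads, or 0.0489 CPM in the male and 0.0460 in the female library.

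Of the 36 gene lists, written before the data were examined, 32 name their members and 4 use symbol patterns. Members were matched by current symbol, then the table's symbol, then a synonym held by a single gene. The members tpx2, cart1 and crp were left out after the match was seen, because it led to other genes. Each list with at least 5 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean expression, and called apart under percentile 2.5 or over 97.5. The mitochondrial genome pattern had no measured member. The genes named follow a rule also written before the data were examined: 16 reproductive genes given whatever their values, the top 12 genes with established symbols and the top 2 provisional genes per direction, ranked by the interval end nearest 1, up to 4 passing members per list by the same ranking or, with none, the 2 with the highest mean, and the 5 genes with most reads per library. Other members are named as examples and were chosen after their values were seen.

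The calculation was tested on simulated counts for 14750 genes, 200 of them changed. The counts were drawn with counting noise alone, without any spread between fish or libraries. The test therefore checks the calculation only and gives no rate of false calls for the real libraries. Genes changed 3-fold, 4-fold, 8-fold and 16-fold were all recovered (50 of 50 each), 0 of 14550 unchanged genes were called, and 95.2% of intervals held the true ratio. Of 40 unchanged lists, 1 fell outside the random lists, and all 20 lists moved by 0.5 did. Alternatives were edgeR's TMM factors, library totals, the deposited normalized values, other minimum levels and folds, removal of a lowess trend (fraction 0.3) on genomic span or on expression, another added count, and for lists the mean or the median without the most extreme member. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.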

Results

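RNA sequencing measured messenger RNA in whole brain of wild-type zebrafish, with 1 library from males and 1 from females. Each library was made from the pooled brains of 5 fish. The estimated counts summed to 62248792 in the male library and 64300988 in the female library, spread over 27423 rows of the table. Read counts below are these estimated counts, rounded, and the intervals treat them as whole reads. Summing rows that share an Entrez ID gave 27095 genes, of which 14756 reached a mean of 1 CPM, counts scaled to a common library size, and are called measured here. No gene took more than 0.125% of the male or 0.134% of the female reads. With 1 library per sex there is no spread between replicates, so no test was made, no difference below has a replicate check, and each interval is a 95% interval that covers counting error only. Ratios are log2 of male over female, so a negative value is higher in the female library, and read counts are given male before female.

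The comparison asked which genes differ in expression between the male and the female brain. The 2 libraries were close for most genes, and the largest differences were in genes best known from other tissues. Vitellogenin genes, which encode yolk precursor proteins made in the liver under oestrogen, were far higher in the female library, with vtg1 at 189 against 58659 reads (log2 ratio -8.19, interval -8.40 to -7.98). Many genes of the egg coat and liver-made proteins, and the elastase genes ela3l and ela2l, were higher on the same side. The male library was higher for photoreceptor genes such as rho (6.10-fold, interval 5.27 to 7.13), for telencephalic transcription factors such as foxg1a (1.85, interval 1.74 to 1.96) and for some keratin genes. The brain aromatase gene cyp19a1b, which makes oestrogen in radial glia, was level at 34072 against 35722 reads (0.02, interval -0.00 to 0.04).

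Under the rule of size, a mean of at least 1 CPM, at least a 2-fold difference and a counting interval that excludes 1, 156 genes were higher in the male library and 399 in the female library. The other 14201 measured genes, 96.2%, met neither. The median absolute log2 ratio was 0.13, against 0.03 for 2 libraries simulated with counting noise alone, and 88.9% of measured genes lay within 0.5 of 0. At 8-fold or more there were 108 genes on the female side and 7 on the male side. Removing the trend of the ratio with expression level changed the split to 203 male and 328 female genes, so the male share of the calls went from 28.1% to 38.2%. The genes with most reads in either library were the synaptic gene snap25a (log2 ratio -0.05), the kinesin gene kif1a (0.25), ndrg4 (-0.02), the neuronal sodium pump gene atp1a3a (0.09), gpm6aa (-0.07) and the calcium channel gene cacna1ab (0.03), whose sign turned after scaling by library totals or removal of the trend with gene span or expression.

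**Figure D1:**
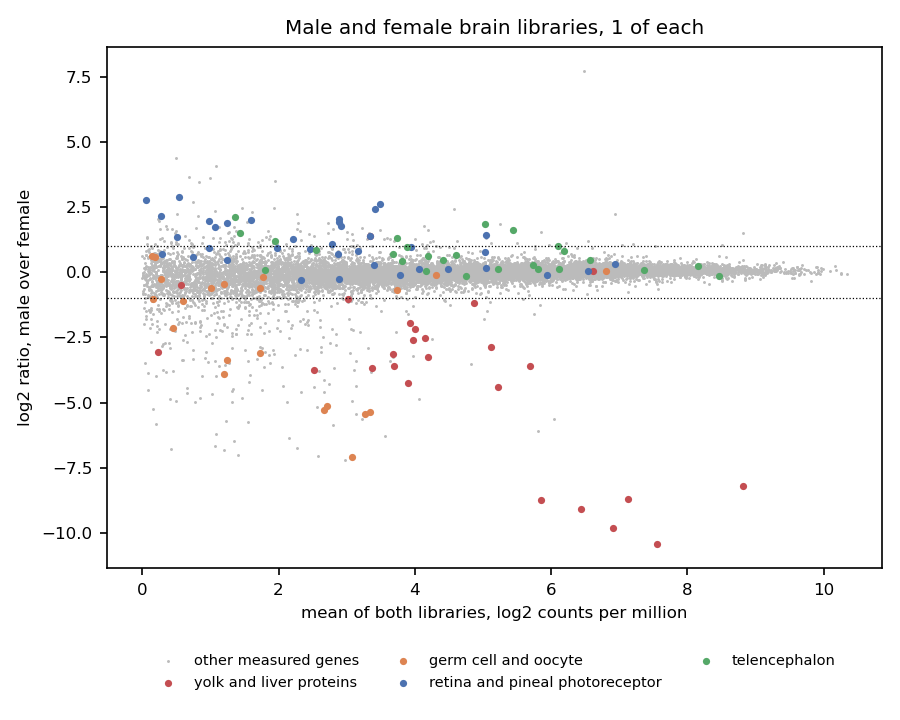
Log2 ratio of male over female for each measured gene (points) against the mean of the 2 libraries in log2 CPM, with dotted lines at 2-fold and members of 4 gene lists in colour. Yolk and liver genes reach -10.44 (vtg2) while photoreceptor genes lie mostly above 0.

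At the minimum of 1 CPM, though not at 5 CPM, yolk and liver proteins formed the list farthest from 0. Of its 25 measured members, 22 were higher in the female library, 1 in the male library and 2 in neither, and the median log2 ratio of -3.25 lay below all 10000 random lists matched on expression (percentile 0). The leading members were vtg2 (16 against 24406 reads, log2 ratio -10.44, interval -11.29 to -9.79), vtg4 (-9.79, interval -10.65 to -9.14), vtg7 (-9.09, interval -9.86 to -8.48), vtg6 (-8.75, interval -9.60 to -8.09) and vtg5 (-8.69, interval -9.19 to -8.27). These genes and vtg1 lie close together on the minus strand of chromosome 22 (Zv9), from vtg1 at 25203630 to vtg2 ending at 25353294. Apart from vtg2 these are closely similar copies, so the share of reads given to each of those is uncertain, although all pointed the same way. The divergent vtg3 on chromosome 11 stood at 92 against 1860 reads (-4.24). Liver-made transcripts other than vitellogenins were also higher in the female library, among them the transferrin gene tfa (-3.59), the fibrinogen gene fgb (-3.13) and the liver fatty acid binding gene fabp10a (-2.59). The complement gene c3b, outside the list, stood at 18 against 1524 reads (-6.28, interval -7.07 to -5.65). The male-side member was rbp4l (901 against 362 reads), which the photoreceptor list also holds.

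Germ cell and oocyte genes were higher in the female library for 11 of 21 measured members and for none in the male library, with a median of -1.03 (percentile 0). At a minimum of 5 CPM, which left 8 members, the median was -5.20. That minimum is on the mean of both libraries, so a gene can pass through the female library alone, as zp3a.1 did at 0.114 against 16.8 CPM. The lower median is therefore no separate check of the list. Egg-coat glycoprotein genes led, with zp3a.1 at 7 against 1096 reads (log2 ratio -7.10, interval -8.52 to -6.15), zp2.2 at 26 against 1227 (-5.44, interval -6.09 to -4.91), zp3 at 29 against 1292 (-5.36, interval -5.97 to -4.86) and zp3a.2 at 19 against 808 (-5.29, interval -6.06 to -4.67). The related zp3.1 stood at 22 against 1197 (-5.65, interval -6.36 to -5.07). Reads can be shared between copies of this family, and the values of single copies are uncertain. The oocyte gene zar1 stood at 25 against 283 (-3.39). Members that did not pass included the meiotic gene sycp1 (-0.18) and the Piwi gene piwil1 (-0.47). Other female-side leaders were the claudin gene cldnd, at 2 against 297 reads (-6.81, interval -10.18 to -5.26), and the provisional genes zgc:171750 (6 against 1018, -7.20) and zgc:171977 (5 against 778, -7.06), close together on chromosome 24. Their similar names and positions leave open how reads were divided between them.

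The exocrine pancreas and gut list was higher in the female library for 8 of 25 measured members and in the male library for 1. Its median was -0.60 (percentile 0), or -0.36 at a minimum of 5 CPM. The list also holds keratin genes such as krt4, krt5 and krt91, so its median is not one of pancreas and gut alone. The elastase genes ela3l (39 against 330 reads, -2.98, interval -3.51 to -2.51) and ela2l (-2.36, interval -2.80 to -1.96) and the secretory cell gene agr2 (-2.30, interval -2.89 to -1.78) were female-side examples. The member on the male side was the epithelial keratin gene krt4, at 12376 against 2816 reads (2.22, interval 2.17 to 2.28).

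Photoreceptor genes of retina and pineal were higher in the male library for 17 of 37 measured members and for none in the female library. Their median was 0.94, above all matched random lists (percentile 100). The rod opsin gene rho stood at 1179 against 205 reads, the rod transducin gene gnat1 at 1100 against 217 (log2 ratio 2.43, interval 2.22 to 2.65), and the red cone opsin genes opn1lw1 at 157 against 22 (2.90, interval 2.27 to 3.64) and opn1lw2 at 111 against 17 (2.76, interval 2.05 to 3.63). The last pair are neighbouring copies on chromosome 11 that can share reads. The pineal opsin gene exorh was also higher (1.45, interval 1.35 to 1.55), while the cone transducin gene gnat2 was at 0.26. Lens crystallin genes, with 7 measured members, had a median of -0.21 (percentile 27.2, positive without a minimum level) and none passed, with cryba4 at 0.03 and cryabb at -0.70.

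Telencephalic genes were higher in the male library for 7 of 26 measured members and for none in the female library, with a median of 0.55 (percentile 100). Beside foxg1a, the forebrain patterning gene with 3138 against 927 reads, these were emx3 (257 against 62, log2 ratio 2.13, interval 1.73 to 2.56), the pallial gene tbr1b (4035 against 1393, 1.62, interval 1.53 to 1.71), emx1 (1.51, interval 1.16 to 1.88), lhx6 (2.46-fold, interval 2.22 to 2.74), lhx8a (332 against 153 reads) and the pallial gene eomesa (log2 ratio 1.02, under 2-fold when scaled by library totals or with the expression trend removed). In the lists of other regions the median was 0.10 for hypothalamus and preoptic area (27 measured, 1 male-side gene, lhx6 again, percentile 99.7). For midbrain and optic tectum it was -0.04 (24 measured, percentile 17.7), with 1 female-side gene, foxa2. This gene had 88 against 188 reads, at the 2-fold line and under it in 4 of 6 alternatives. The cerebellum median was -0.02 (35 measured, none passing, percentile 2.73). It lay below the random lists at a minimum of 5 CPM, with the expression trend removed or without its most extreme member. The hindbrain and spinal cord list, of Hox genes and others such as mafba and slc6a5, had a median of 0.14 (23 measured, percentile 99.7). Its 1 male-side gene was hoxb1b at 1.08 (interval 0.66 to 1.53). At a minimum of 5 CPM this list lay inside the random lists. In the cerebellum list the genes with most reads were slc17a7, the vesicular glutamate transporter (0.06), and si:ch211-10e2.5, now cbln12 (-0.08). The share of each brain region in each pool was not measured, so the telencephalic values do not show a difference in expression within telencephalic cells.

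**Figure D2:**
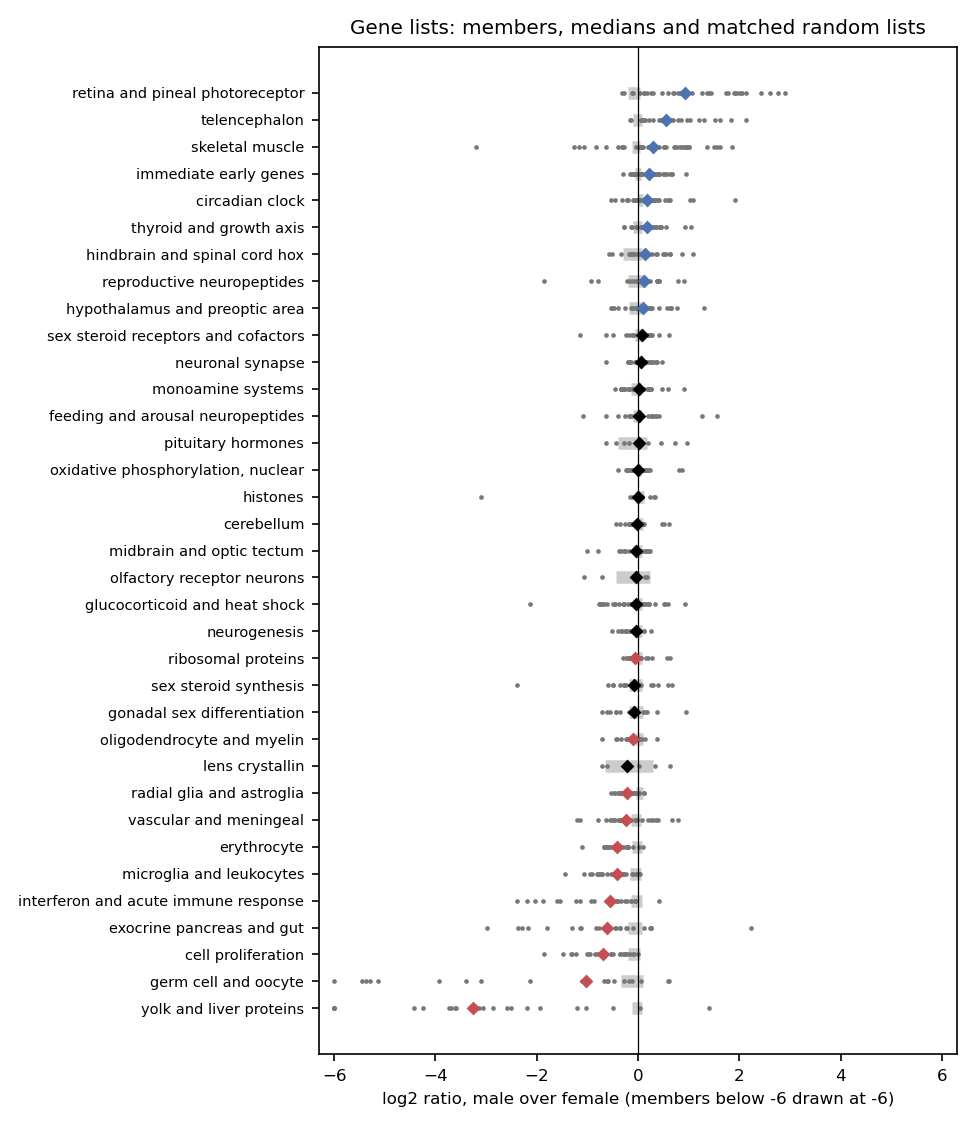
Log2 ratio of male over female for the measured members of each gene list (grey points), the list's median (diamonds; blue for lists above and red for lists below the matched random lists, black otherwise) and the range that holds the central 95% of medians of 10000 matched random lists (grey bars). Yolk and liver proteins have the lowest median, -3.25, and photoreceptor genes the highest, 0.94.

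Among other leading genes on the male side, the provisional gene zgc:136902, now krt93, stood at 10878 against 54 reads (log2 ratio 7.73, interval 7.36 to 8.16), the widest male-side difference. As a keratin it belongs to a family of similar genes, so its count is uncertain. The ionocyte transcription factor gene foxi3b (184 against 15, 3.66, interval 2.95 to 4.57), the anion exchanger gene slc4a1b (200 against 19, 3.45, interval 2.80 to 4.25) and the sodium pump gene atp1a1a.4 (2478 against 486, 5.42-fold, interval 4.92 to 5.99) were higher as well. Further male-side genes were ociad2 (247 against 15, 4.09, interval 3.38 to 4.99), the actinoporin-like gene apnl (2.47, interval 2.12 to 2.85) and zgc:173949 (165 against 8, 4.37, interval 3.44 to 5.69). Skeletal muscle genes went both ways, with 6 male-side and 4 female-side members among 44 measured and a median of 0.29 (percentile 100). The muscle calcium pump gene atp2a1 (1.86, interval 1.76 to 1.96) and the troponin gene tnni2a.1 (1.63, interval 1.49 to 1.76) were higher in the male library, and the parvalbumin gene pvalb1 (-3.20, interval -3.43 to -2.99) and the myosin gene myhc4 (-1.26, interval -1.34 to -1.19) in the female library.

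Genes of sex steroid signalling were largely level. Of 22 measured steroid synthesis genes, 1 passed on the female side, cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis (30 against 170 reads, log2 ratio -2.39, interval -3.03 to -1.85), and the list median was -0.07 (percentile 33.6). Whether the cyp11a1 reads came from brain cannot be told, since germ cell and liver genes were higher in the same library. Gonadal aromatase cyp19a1a was under the expression minimum, with 57 against 49 reads (0.30, interval -0.27 to 0.89). Among 21 measured receptors and cofactors the median was 0.07 (percentile 88.1), and paqr5a, a membrane progestin receptor gene, passed on the female side (-1.15, interval -1.41 to -0.90). The source of the paqr5a reads is open in the same way as for cyp11a1. The oestrogen receptor genes esr1 (0.28, interval 0.12 to 0.44), esr2a (0.41, interval 0.23 to 0.60) and esr2b (0.25, interval 0.09 to 0.41), the androgen receptor gene ar (-0.09, interval -0.16 to -0.01) and the progesterone receptor gene pgr (0.61, interval 0.36 to 0.87) all fell short of 2-fold. None of 19 measured genes of gonadal sex differentiation passed (median -0.08, percentile 26.0), with ctnnb1 at -0.03 and sox9a at -0.18. The testis-linked gene amh stood at 119 against 97 reads (0.38, interval -0.02 to 0.79) and dmrt1 at 8 against 4 (interval -0.81 to 3.27), too few to show a difference.

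Among reproductive neuropeptides and their receptors, 1 of 19 measured genes passed. It was gnrh2, the midbrain gonadotropin-releasing hormone gene, higher in the female library with 132 against 511 reads (log2 ratio -1.86, interval -2.15 to -1.59). As for cyp11a1, whether these reads came from brain cannot be told, since germ cell and liver genes were higher in the same library. The list median was 0.11 (percentile 98.0), a place outside the random lists that was lost at a minimum of 5 CPM, with either trend removed or with the mean. The values were 0.90 for gnrh3 (interval 0.54 to 1.27), 0.80 for kiss1 (interval 0.59 to 1.02), 0.11 for kiss2 (interval -0.19 to 0.41), 0.42 for oxtl, now oxt (interval 0.37 to 0.47), and 0.24 for avpl, now avp (interval 0.09 to 0.40). Feeding and arousal peptides had 2 male-side genes, ghrh (1.26, interval 0.75 to 1.80) and LOC793458, now pyyb (1.56, interval 1.19 to 1.95), and 1 female-side gene, LOC100001008, now urp2 (-1.09, interval -1.34 to -0.85, under 2-fold with the expression trend removed). Their median of 0.02 over 24 measured members (percentile 76.8) turned negative when scaled by library totals. None of 9 measured pituitary genes passed (median 0.02, negative when scaled by library totals or without the most extreme member, percentile 79.2, and above the random lists without a minimum level), with gh1 at -0.27 and drd2a at 0.20.

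Cell proliferation genes were lower in the male library for 31 of 32 measured members, of which 5 passed the rule on the female side. The median was -0.68 (percentile 0), and the mitotic genes plk1 (163 against 625 reads, log2 ratio -1.85, interval -2.11 to -1.60), cdc20 (-1.48, interval -1.77 to -1.20), kif23 (-1.31, interval -1.54 to -1.10) and aurkb (-1.22, interval -1.54 to -0.92) led. The neurogenesis list had a median of -0.05 over 27 measured members (percentile 3.21, and below the random lists at a minimum of 5 CPM or with either trend removed) and none passed, with stmn1b at -0.24 and elavl4 at -0.05. Germ cell and liver genes were higher in the same library.

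Immune lists were also lower in the male library. Interferon and acute immune genes had 8 female-side members of 28 measured and a median of -0.55 (percentile 0), or -0.26 at a minimum of 5 CPM. The leaders were immunoproteasome and peptide transporter genes of chromosome 19, psmb10, now psmb13a (51 against 286 reads, log2 ratio -2.39, interval -2.86 to -1.96), psmb9a (-2.19, interval -2.64 to -1.79), psmb8 (-2.03, interval -2.45 to -1.64) and abcb3l1, now tap2a (-1.88, interval -2.19 to -1.58).

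**Figure D3:**
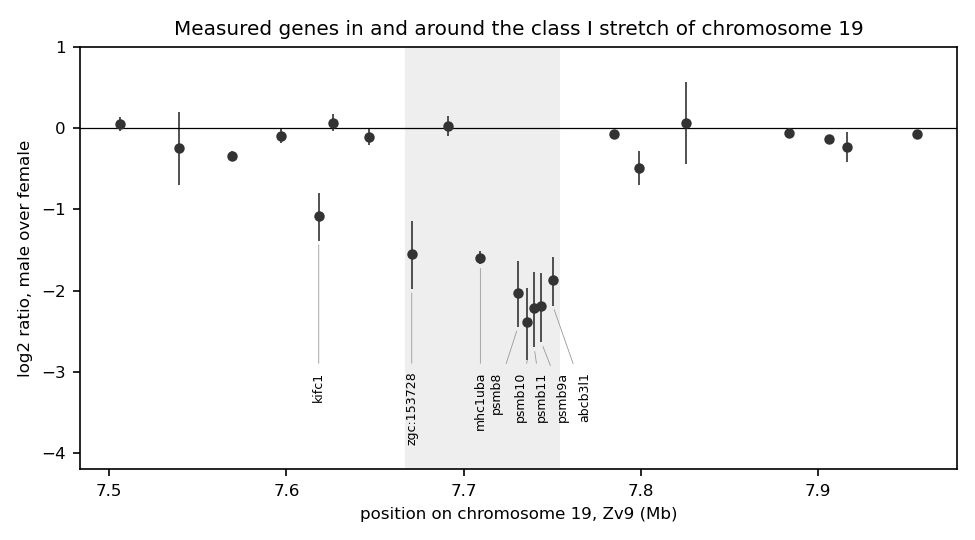
Log2 ratio of male over female (points, with 95% counting intervals as bars) for the measured genes against position on chromosome 19 in Mb (Zv9), with the stretch from 7667511 to 7753903, drawn from its first to its last female-side gene of antigen presentation, shaded. Inside it 7 of 8 genes were higher in the female library, with a median of -1.95, and the 14 genes beside it had a median of -0.11.

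Microglia and leukocyte genes had 2 female-side members of 28, the cathepsin S gene ctssb.1 (-1.45, interval -1.70 to -1.21) and the complement gene c1qc (-1.06, interval -1.32 to -0.81), and a median of -0.42 (percentile 0). Erythrocyte genes had 1 of 21, the embryonic globin gene hbbe2 (-1.11, interval -1.53 to -0.72), and a median of -0.41 (percentile 0). With the expression trend removed, c1qc and hbbe2 lay under 2-fold. Vascular and meningeal genes had 2 of 32, the fibronectin gene fn1b (-1.14, interval -1.24 to -1.05) and mgp (-1.21, interval -1.64 to -0.80), and a median of -0.24 (percentile 0).

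Several lists had a median outside the matched random lists with few or no members reaching 2-fold. None of 29 measured radial glia and astroglia genes passed (median -0.22, percentile 0), with the glutamate transporter gene slc1a2b at -0.21, and none of 23 oligodendrocyte genes (median -0.09, percentile 0.065), with mpz at -0.17 and mag at -0.03. By their mean these lists, and the vascular and ribosomal ones, lay inside the random lists. None of 45 immediate early genes passed (median 0.22, percentile 100), and the activity-driven genes npas4 and egr1 were at 0.41 and 0.08. The circadian list had 3 male-side genes of 41, the repressor genes nr1d1 (10835 against 5660 reads, 1.03, interval 0.98 to 1.07, under 2-fold when scaled by library totals or with the expression trend removed) and nr1d4b (1.09, interval 1.04 to 1.13) and the melatonin enzyme gene aanat2 (1.91, interval 1.69 to 2.15), with a median of 0.18 (percentile 100). In the thyroid and growth list dio2, which activates thyroid hormone, was the male-side gene of 25 (1.04, interval 0.98 to 1.11), and the median was 0.17 (percentile 99.99). The ribosomal pattern, in which 6 of 83 measured genes are S6 kinases, had none passing and a median of -0.05 (percentile 0), with rplp0 and rpl4 both at -0.04, although rpl4 turned positive when the trend with gene span was removed. The ribosomal median was -0.01 with that trend removed and -0.10 with the expression trend removed, below the random lists each time.

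The remaining lists lay within the matched random lists. Neuronal synapse genes had a median of 0.05 over 37 measured members (percentile 45.4, negative after removal of the trend with expression), with syt1a at 0.21. Monoamine genes had a median of 0.03 over 32 (percentile 92.4, negative when scaled by library totals), with adra2a at 0.21 and mao at -0.10. Nuclear oxidative phosphorylation genes had a median of 0.00 over 100 (percentile 19.2, with a sign that changed with the scaling), with sdha at -0.14 and zgc:111961, now atp5f1b, at 0.03, which turned negative when scaled by library totals or with the expression trend removed. None of these lists had a passing gene. Olfactory receptor neuron genes had 1 female-side gene of 5, the olfactory marker gene ompa (-1.07, interval -1.38 to -0.77, under 2-fold with the expression trend removed; list median -0.04, percentile 47.7, but -0.80 and below the random lists without a minimum level). Glucocorticoid and heat shock genes had 1 of 45, the collagen chaperone gene hsp47 (-2.12, interval -2.45 to -1.82, median -0.04, percentile 3.35, and below the random lists with the expression trend removed). Histone genes had 1 of 14, LOC100332229, an oocyte-type histone gene now named h2af1al (-3.10, interval -3.61 to -2.66), with a median of -0.00 (percentile 21.9, positive without a minimum level, at 5 CPM, with the span trend removed or without the most extreme member). In all, 9 lists lay above and 11 below the matched random lists out of 35 with a percentile, where 1.75 would fall outside by chance if members were independent, which genes of a list are not.

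Many genes could not be compared. Of the rows, 10440 (38.1%) were listed at 0 in both libraries, including all 37 of the mitochondrial genome. The shares that follow leave out 4 long unbroken stretches at 0 that reach the last row of a chromosome, the mitochondrial genome among them. Outside these, 69.8% of rows with LOC symbols and 9.96% of named genes were at 0. Other stretches at 0, such as 49 rows on chromosome 10, are counted in these shares. Among the named genes at 0 was gnb2l1, a ribosome component every cell uses, so a value of 0 does not show that a gene is silent.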

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

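The alternatives in this part were planned before the data were examined, except those on unsummed rows, the interval requirement and left-out lists, which were chosen after seeing the data. The counts of 156 male-side and 399 female-side genes depended most on the minimum level and the fold. Without a minimum level they were 319 and 656, with at least 5 CPM 59 and 112, at 1.5-fold 413 and 899, and at 4-fold 27 and 182. By construction these settings let in or drop genes. Other scalings and trend corrections gave 143 to 203 male-side and 328 to 428 female-side genes. With each row kept apart there were 158 and 400, and without the interval requirement 156 and 399. Leaving out the photoreceptor, telencephalon and muscle lists left 126 male-side genes, and leaving out the yolk and liver, germ cell and gut lists left 358 female-side genes. The number of lists apart from the random lists was 20, and 15 to 22 under the alternatives. With the mean in place of the median, the radial glia, oligodendrocyte, vascular, ribosomal and reproductive neuropeptide lists were no longer apart. The reproductive neuropeptide list also fell inside at 5 CPM and under both trend corrections, and the hindbrain and spinal cord list at 5 CPM. Others came to lie apart: cerebellum at 5 CPM, with the expression trend removed and without its most extreme member, neurogenesis at 5 CPM and under both trend corrections, glucocorticoid and heat shock with the expression trend removed, and pituitary and olfactory lists without a minimum level. Of the list medians under the alternatives, 19 moved by more than the spread of random lists and 257 did not. The germ cell median was -5.20 at 5 CPM, interferon -0.26 and exocrine -0.36. Without a minimum level the olfactory median was -0.80 and the hindbrain and spinal cord median 0.37.

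Scaling by library totals moved the median of all measured genes to -0.04. Of the 109 named genes, 67 passed the rule of size and none of these changed direction under any of the 6 alternatives run on single genes. Calls of 6 of them ended, all genes close to 2-fold. With the expression trend removed foxa2 was at -0.83, hbbe2 -0.93, c1qc -0.93, ompa -0.92, urp2 -0.96 and nr1d1 0.97. Scaling by library totals put nr1d1 at 0.98, and foxa2 also lost its call with the deposited normalized values, the span trend removed (-0.97) or 5 added to each count (-0.96). Of genes named as examples, kifc1 (-0.94 with the expression trend removed) and eomesa (0.98 by library totals, 0.99 with that trend removed) lost theirs. The largest move was 1.46 for cldnd with 5 added to each count, where the male library had 2 reads. Level genes near 0, cyp19a1b among them, changed sign under library totals or a trend correction. The alternative on RPKM values was not run, since the table used here has no such column. Exon lengths were not used here, so the length trend was fitted on genomic span. No paired analysis was possible because each sex has 1 library. Depth limits genes with few reads, such as dmrt1 with 8 against 4.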

Other observations

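All tests of explanations in this part, and the bounds by which each was judged, were chosen after the results were seen, and the gene sets used only here were written after the data were examined. Epidermal and ionocyte genes had a median log2 ratio of 0.33 over 21 measured genes (percentile 100), but the set includes genes already seen to differ, so that place is favoured by the choice. Of these genes 8 were higher in the male library, among them krt15 (1.31), krt96 (1.31) and krt94 (7936 against 3671 reads) beside krt93 and foxi3b, while cldne (-2.16) and agr2 (-2.30) were higher in the female library and the other 11 lay between -0.83 for krt91 and 0.67 for gcm2, among them the basal cell gene tp63 at 0.27, krt5 at 0.26, and the ionocyte genes ca2 at 0.07 and trpv6 at -0.23. A set of 6 measured regional telencephalon genes, picked largely from those already seen to differ, had 5 higher in the male library and a median of 1.57. The olfactory marker gene ompb, under the expression minimum and so not called, stood at 7 against 100 reads (-3.66, interval -5.10 to -2.65). Genes of chromosome 4, which carries the sex-linked region of natural zebrafish strains, had a median of -0.01 over 529 measured genes (percentile 46.2). Of its 1335 rows, 673 (50.4%) were at 0 in both libraries, in part in unbroken runs between 36454002 and 57290135. The median does not cover these rows, so it does not settle whether genes of the sex-linked region differ. Medians of the other chromosomes lay between -0.08 on chromosome 7, with 28 measured genes, and 0.02 on chromosome 10. Chromosomes 10 (percentile 98.6), 17 (median 0.02, percentile 98.4) and 16 (median -0.02, percentile 1.37) lay outside the central range of matched random sets, by small amounts.

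Rows listed at 0 in both libraries formed long unbroken stretches. From 6819342 on chromosome 7, all 1319 rows to the last at 77267489 were at 0, as were 432 rows from 27177358 on chromosome 23 and 179 rows from 39690445 on chromosome 12. With the mitochondrial genome these make 1967 rows. They hold the ribosomal protein genes rps26, rps12, rpl13, rpl34, rps20, rps13, rpl38 and rps4x. In 139 rows the value was 0 in 1 library only, and the largest value opposite such a 0 was 76.5 reads.

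The vitellogenin and egg-coat genes higher in the female library may reflect tissue other than brain in that pool. Liver-made transcripts other than vitellogenins had a median log2 ratio of -2.73 over 18 measured genes, 15 of them passing. This fits liver RNA carried into the pool, but these genes belong to the list already seen to differ, so the result partly restates the pattern. Germ cell genes other than egg-coat genes had a median of -0.60 over 15, with 6 passing and values from -3.92 to 0.61. That median is close to the bound of -0.5 set after the value was known, and ovarian RNA remains a candidate source. The egg-coat genes themselves were left out of it, and liver-made transcripts do not address where egg-coat transcripts came from. These medians therefore do not rank ovary against liver. For a stronger oestrogen response of female brain cells, cyp19a1b, esr1 and pgr were examined. Their median was 0.28, and none was higher in the female library. Genes of the telencephalon also differed between the pools, so these 3 genes from 1 pool per sex cannot decide the question. The sex of the fish sets vitellogenin levels in liver, and 1 pool per sex leaves open whether such a carry-over would recur.

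The photoreceptor genes higher in the male library may come from retinal tissue in the male pool, but the median of 2.68 over 4 retinal opsin and rod transducin genes restates the pattern, and 6 measured retinal pigment epithelium genes outside the photoreceptor list had a median of 0.81, from -0.16 to 1.67, which leaves it open (0.22 and percentile 97.1 over all 9 measured). More pineal tissue stays open too, since exorh at 1.45 and the rest of a pineal set of 5, with a median of 1.73 and asmt2 at 0.12, are themselves members of the photoreceptor list. A different hour of sampling could not be decided: genes of the positive clock arm had a median of 0.38 and those of the negative arm and outputs 0.30, but the latter ran from -0.54 for per3 to 1.09 for nr1d4b. The hour of dissection is not given in the sources used here. A difference between the sexes in these tissues was not tested.

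The immune genes higher in the female library on chromosome 19 lie within 86.4 kb (Zv9, 7667511 to 7753903), where 7 of 8 measured genes passed and the median was -1.95, among them the class I genes zgc:153728, now mhc1uka (-1.55), and mhc1uba (-1.60) and the proteasome gene psmb11, now psmb12 (-2.21), with tapbp.2 at 0.03 as the exception. The 14 measured genes within 200 kb on either side had a median of -0.11, and 1 of them, kifc1, passed, though not with the expression trend removed (-0.94). A stronger interferon response in the female pool stays open. The 22 measured interferon list members elsewhere had a median of -0.41, from -1.23 to 0.42, with 2 passing. More leukocytes stay open too, with a list median of -0.42. Both medians were smaller than that of the stretch but on the same side. These lists also hold acute immune and microglia genes, which need not move as far as the genes of the stretch, so the medians cannot decide. A difference of haplotype between the pools, which could change how many reads match the reference, stays open, as the stretch was drawn from its first to its last female-side gene and its level flanks therefore decide nothing. Reads were not analysed here, so a difference in expression between the pools or the sexes stays open as well.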
